A study of Homo sapiens with 21 samples.

How the data were processed

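RNA levels were measured on 21 human microarrays in a time course of rotenone, an inhibitor of respiratory chain complex I. Per the labels, the material was total RNA whose source is given only as brain with no further detail, and no dose of rotenone is given. The labels place 3 samples in each of 6 groups: untreated (labelled with week 1), control at 1, 2 and 4 weeks, and rotenone at 1 and 4 weeks. The rotenone group at 2 weeks has 3 arrays from 2 extracts, because replicate A was labelled and hybridised again. Its arrays were averaged on the log2 scale and counted as 1 sample, which left 20 samples. Replicate letters come from the sample titles. The description of rotenone 4 weeks B carries the letter C, and that of control 4 weeks A carries no letter. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

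The deposited values are intensities on a linear scale, 1 per probe set and array, for 54675 probe sets. They ranged from 0.0402 to 27582.9 and none was negative. From the deposited values, the mean intensity after leaving out the lowest and highest 2% of probe sets was 150.02 on every array. This is the pattern of a global scaling of each array by 1 factor. The software that made the intensities, and any background correction, are not given in the sources used here. Medians of the log2 values differed by at most 0.25 between arrays, below the limit of 0.5 set for further normalization, so the deposited scaling was kept. No column of sample values was left unused. The number of arrays limits the precision; these intensities carry no counting depth.

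Probe sets were named through the platform's probe annotation table, which lists 42898 of them. Of these, 41097 have 1 gene and 1801 have several genes. A further 11777 probe sets are unnamed here. Symbols were updated through Entrez identifiers in the RefSeq gene table of assembly GRCh38.p14 for 41043 of the 1-gene probe sets. No genome sequence was used and no coordinates are given. Control probe sets (62) were left out of the tests. A gene was represented by its probe set with the highest mean over all arrays, which gave 19775 genes. Probe sets shared by several genes were not used here. Of 472 pairs of a named gene and a comparison (control 2 weeks against the other control weeks included), 258 had another probe set above the intensity filter. In 187 of these, the other probe sets all changed in the same direction, and in 2 another probe set passed in the opposite direction.

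Values were analysed as log2(intensity + 16), so fold changes of dim genes are understated. Genes whose mean lay under the 40th percentile of all probe sets (log2 value 5.13, intensity 19.0 before the pseudocount) were left out, and 14157 genes were tested. Each gene was fitted with limma (version 3.58.1, R 4.3.3) using 1 mean per group (7 groups, 13 residual degrees of freedom) and moderated statistics with an intensity trend. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 counted as passing. The comparisons were rotenone against control at 1, 2 and 4 weeks, the mean of these differences, the differences between weeks of the rotenone effect, control 4 weeks against control 1 week, and control 1 week against untreated. Changes are log2 differences with standard errors (SE), and group levels are log2 means with SD.

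Gene lists (32) were tested as sets with camera in limma, at a preset correlation between genes of 0.01 and again with the correlation estimated from the data. P-values were adjusted over 128 tests for the rotenone comparisons and 160 for the others. The lists cover complex I, complexes II to V, mitochondrial biogenesis and import, glycolysis, hypoxia targets, NRF2 targets, other antioxidant enzymes, ATF4 and amino acid stress targets, endoplasmic reticulum (ER) chaperones, cholesterol synthesis, p53 targets, cell cycle, proteasome, cytosolic heat shock proteins, tubulins and microtubule proteins, catecholamine neuron genes, Parkinson disease genes, neuronal and synaptic genes, BCL2 family and caspases, autophagy and lysosome, interferon response, inflammatory and NF-kB targets, immediate early genes, metallothioneins, extracellular matrix, cytosolic ribosomal proteins, and fatty acid oxidation with the tricarboxylic acid cycle. Markers of astrocytes, oligodendrocytes, microglia and macrophages, endothelium, and mesenchymal or fibroblast-like cells were included. Each list was counted member by member over all genes tested and adjusted over the list alone. Its median was also compared with 10000 random lists matched on expression, and its mean per sample was compared by an exact permutation test of the rotenone and control labels within weeks (4000 splits, either direction).

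The groups, the comparisons, the lists, the main settings and the naming rule were fixed before the data were examined. For each rotenone comparison, the rule names the 12 largest rises and 12 largest falls among passing genes whose rotenone samples all lay on 1 side of the controls of that week. For the mean over the weeks, it asks for the same sign in all 3 weeks. Other comparisons have 5 in each direction. For each list, up to 4 passing members of largest change are named, or 2 of smallest p where none passed. XIST and Y-linked genes (14 of the tested genes) are never named. Alternatives were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, median centring, the mean of all probe sets of a gene, no intensity trend, array weights, only the 2 groups compared, untreated and control 1 week pooled, the second labelled extract kept apart or left out, a replicate block, and each replicate left out in turn. Leaving out 1 week, the matched lists and the permutation of list means were added after the data had been seen.

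The gene test was tested on simulated data for the same 14157 genes, with 100 genes changed by 0.5 and 100 by 1 on the log2 scale. At 1 week it recovered 36% and 69% of them. At 2 weeks it recovered 27% and 50%, and at 4 weeks 22% and 73%. Of the genes called, 3 of 108, 8 of 85 and 3 of 98 had not been changed. In the list test at 4 weeks, a list shifted by 0.30 was called and 0 of 124 other tests passed. The simulated values were independent between genes and the lists were random. The list simulation therefore does not show how often lists of correlated genes pass without a shift. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.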

Results

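Gene expression was profiled in 20 samples on 21 arrays: untreated samples, and control and rotenone samples at 1, 2 and 4 weeks, with 3 samples in each group except rotenone at 2 weeks, which had 2. Rotenone blocks complex I of the mitochondrial respiratory chain. Pairs of arrays within a group correlated at r = 0.970 to 0.981 over 19 pairs (r across genes, which are not independent replicates), and the lowest correlation between groups was 0.959. Both labelled extracts of rotenone 2 weeks A correlated at 0.976, while they correlated with replicate C at 0.981 (first) and 0.975 (second). The SD of their log2 difference was 0.43, against 0.39 to 0.47 in the 19 pairs. In this 1 case, labelling an extract again thus gave a spread like that between replicates. The difference between the 3' and 5' control probe sets of ACTB, a sign of RNA quality, was 0.68 (log2) in rotenone 4 weeks B and 0.23 to 0.42 on the other arrays. For GAPDH it was 0.18 in that sample and 0.15 in control 4 weeks B, the next highest. The first principal component held 13.7% of the variance.

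At 1 week, lists of cytosolic heat shock proteins, cholesterol synthesis and mesenchymal markers were higher in rotenone than in control samples. DNAJB1, a cochaperone of HSP70, rose 2.84-fold (SE 0.086 on the log2 scale, n = 3 against 3, adjusted p = 5.0e-11), from 9.75 ± 0.068 (SD) in controls to 11.25 ± 0.032; untreated samples stood at 11.02 ± 0.020, and rotenone 1 week samples did not pass against them (0.23, adjusted p = 0.19). ADM, which encodes the vasoactive peptide adrenomedullin, rose 3.01-fold (log2 change 1.59 ± 0.18 SE, adjusted p = 2.8e-05), and CCN1, a matricellular protein encoded by an immediate early gene, rose 2.32-fold (1.22 ± 0.081, adjusted p = 7.8e-10). In all, 191 of 14157 genes changed, 137 up and 54 down, and 2093 genes had an unadjusted p under 0.05. Of the 191 genes, 190 had rotenone samples all on 1 side of the controls, as did 19.8% of all tested genes against 10% by chance.

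The other large rises at 1 week were AFF2 (1.23), the inducible HSP70 gene HSPA6 (1.19), ARHGDIB (1.05), the small GTPase RRAS (0.97), the transcription factor SNAI2 (0.79), CMC4 (0.79), TAGLN2 (0.79), the actin-binding peptide TMSB4X (0.76) and the small heat shock protein HSPB1 (0.74). The large falls were EPN1 (-1.61), ZGRF1 (-1.51), LEFTY1 (-1.49), SLN (-1.47), HELZ2 (-1.47), TNXB (-1.42), ALPK3 (-1.40), CEACAM3 (-1.30), TYR (-1.22), LOC100505715 (-1.21), KRT7 (-1.14) and MPP3 (-0.99). These falls were of dim genes, with mean levels from 5.19 (LEFTY1) to 6.57 (KRT7). Against untreated samples, HSPA6 in rotenone 1 week samples was not higher (-0.50, adjusted p = 0.18). With each replicate left out in turn, 7 of the 12 rises and 1 of the 12 falls (EPN1) passed throughout.

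At 1 week, 16 of the 32 lists were shifted, all upward, and 5 held with an estimated correlation. ER chaperones, not shifted here (median -0.043), were shifted downward at 1 week under quantile normalization (adjusted p = 0.0032) and lay at percentile 1.05 of lists matched on expression. Cholesterol synthesis had 5 of 18 measured members higher and 0 lower (9 higher adjusted over the list alone), with ACAT2 at 0.67, MSMO1 at 0.67, INSIG1 at 0.65 and FDPS at 0.55. Its median was 0.29 (adjusted p = 1.5e-04 with an estimated correlation). Among mesenchymal and fibroblast-like markers 6 of 18 rose, 9 adjusted over the list alone, including ANXA1 (0.56), DCN (0.52) and VIM (0.48), with a median of 0.35 (adjusted p = 7.8e-04 with an estimated correlation). Of 16 cytosolic heat shock proteins, 2 rose (DNAJB1 and HSPB1; 6 adjusted over the list alone), with a median of 0.21 and adjusted p = 0.015 with an estimated correlation. Of 30 tubulins and microtubule proteins 4 rose (5 adjusted over the list alone): TUBA1A (0.73), MAPRE2 (0.47), TUBB2A (0.47) and TUBB3 (0.41), with adjusted p = 0.049 with an estimated correlation. The cell cycle list had 3 of 41 members higher (8 adjusted over the list alone), TYMS (0.47), CCNB2 (0.38) and RRM2 (0.32), and adjusted p = 0.048 with an estimated correlation.

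Both lists of respiratory chain genes were shifted upward at 1 week at the preset correlation only. Of 33 complex I subunits, 3 rose (NDUFA13 0.43, NDUFS4 0.43, NDUFS6 0.40), 17 adjusted over the list alone, and the list median was 0.26 (adjusted p = 0.077 with an estimated correlation). Of 35 subunits of complexes II to V, 5 rose (10 adjusted over the list alone), such as UQCR11 (0.48), UQCRQ (0.46), ATP5PD (0.41) and COX5B (0.39), with adjusted p = 0.18 with an estimated correlation. ATP5PD reversed to -0.085 when its probe sets were averaged. Of 27 proteasome subunits 3 rose (PSMA7 0.35, PSMB2 0.34, PSMC1 0.31), 16 adjusted over the list alone, with a median of 0.22 and adjusted p = 0.053 with an estimated correlation. Bright genes shifted upward as a class: the median change went from -0.15 among the dimmest 20% of genes to 0.055 among the brightest 20%. Random lists matched on expression had medians of 0.067 for complex I and 0.080 for the proteasome.

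Another 8 lists were shifted upward at 1 week at the preset correlation only. Of 20 glycolysis genes 1 rose (PGAM1 0.30; 3 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation), of 24 NRF2 targets 2 rose (SLC7A11 0.39, TXN 0.33; 3 over the list alone; 0.056 likewise), and of 29 other antioxidant enzymes 3 rose (GSTP1 0.49, GSTM3 0.40, SOD1 0.38; 11 over the list alone; 0.071 likewise). ATF4 and amino acid stress targets had 3 of 33 higher (ATF3 0.46, ASNS 0.41, GARS1 0.30; 4 adjusted over the list alone; adjusted p = 0.058 with an estimated correlation). ATF3 reversed to -0.079 when its probe sets were averaged. Immediate early genes had 3 of 26 higher, with DUSP1 at 0.46 (6 adjusted over the list alone; 0.11 likewise), and extracellular matrix genes had 5 of 32 higher, with SPARC at 0.64, LUM at 0.43 and COL5A2 at 0.39 (7 adjusted over the list alone; 0.051 likewise). The median of the extracellular matrix list was 0.00020, at percentile 71.6 of lists matched on expression, so its median did not shift. Which members carry the call was not tested. Of 32 fatty acid oxidation and tricarboxylic acid cycle genes 2 rose (IDH2 0.70, ETFB 0.61; 6 over the list alone; 0.077 likewise). Of 32 cytosolic ribosomal proteins 0 passed, and that list's median of 0.076 lost its call with an estimated correlation (adjusted p = 0.67), under quantile normalization (0.53) and without rotenone 1 week A (0.082) or B (0.47). Against lists matched on expression, the medians of ATF4 targets (percentile 91.7) and ribosomal proteins (20.6) did not stand out either.

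Single samples moved the count at 1 week: it was 27 without rotenone 1 week B, 46 without rotenone A, 39 without control 1 week C, 68 without control B and 118 without control A. Median centring of the arrays moved the median change of all genes from -0.035 to 0.070, and the split from 137 up and 54 down to 215 up and 10 down.

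At 2 weeks (2 rotenone samples against 3 controls) ER chaperones were lower, and the cholesterol synthesis and cell cycle lists were higher. Of 24 ER chaperones and unfolded protein response genes, 8 fell and 0 rose (18 lower adjusted over the list alone), among them SDF2L1 (-0.76), DNAJC3 (-0.68), MANF (-0.66) and DNAJB9 (-0.63). The list median was -0.33 (adjusted p = 1.2e-04 with an estimated correlation). FDPS, which makes farnesyl diphosphate, rose 1.82-fold (0.86 ± 0.095 SE, adjusted p = 1.7e-05), and the cystine transporter gene SLC7A11 rose 1.80-fold (0.85 ± 0.11, adjusted p = 5.1e-05). RAD51AP1, which acts in homologous recombination, rose 2.39-fold (1.25 ± 0.14, adjusted p = 1.7e-05). Of 169 changed genes, 116 were higher and 53 lower, and 1626 had an unadjusted p under 0.05. All 169 had rotenone samples on 1 side of the controls, as did 32.7% of all tested genes against 20% by chance.

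The other large rises at 2 weeks were PLEKHN1 (1.73), the chemokine CXCL10 (1.30), SAMD4A (1.12), the transcription factor BHLHE22 (1.10), the small GTPase RHOB (1.10), CBR4 (1.09), LINC00968 (1.07), the kinetochore gene SPC24 (1.02), HMGA2 (1.00), KLF15 (0.97) and CCDC71L (0.96). The large falls were DERL3 (-1.35), which acts in ER-associated degradation, NBAS (-0.91), COLEC11 (-0.86), the lysosomal glycoprotein GPNMB (-0.82), EPB41L4A-AS1 (-0.81), the collagen prolyl hydroxylase P4HA2 (-0.75), CYFIP2 (-0.74) and ANKRD37 (-0.66), besides SDF2L1, DNAJC3, MANF and DNAJB9. With each replicate left out in turn, 3 of the 12 rises (RAD51AP1, BHLHE22, RHOB) and 3 of the 12 falls (NBAS, EPB41L4A-AS1, MANF) passed throughout.

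At 2 weeks, 9 lists were shifted, 6 upward and 3 downward, and 4 held with an estimated correlation. Cholesterol synthesis had 2 of 18 higher (FDPS and ACAT2, at 0.78; 3 adjusted over the list alone; adjusted p = 0.0051 with an estimated correlation). The cell cycle list had 9 of 41 higher (15 adjusted over the list alone), with CDC45 at 0.89, KIF23 at 0.55, CENPE at 0.53 and TYMS at 0.53, and the same adjusted p = 0.0051 with an estimated correlation. Mesenchymal markers had 2 of 18 higher (DCN 0.56, COL3A1 0.48; 7 adjusted over the list alone; adjusted p = 0.034 with an estimated correlation). Of 32 cytosolic ribosomal proteins 0 passed over all genes and 20 were lower adjusted over the list alone, with a median of -0.23 against -0.16 in lists matched on expression. That call was lost with an estimated correlation (adjusted p = 0.18) and under quantile normalization (0.13).

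The remaining shifted lists at 2 weeks lost their call with an estimated correlation. ATF4 and amino acid stress targets had 4 of 33 higher, VLDLR (0.82), ATF3 (0.66), CTH (0.52) and PSPH (0.45), 7 adjusted over the list alone (adjusted p = 0.21 with an estimated correlation; 0.14 without control 2 weeks C or without rotenone C). Extracellular matrix genes had 3 of 32 higher, with COL5A2 at 0.38 (7 adjusted over the list alone; 0.084 likewise; 0.086 without control C, 0.089 without rotenone A). Of 29 other antioxidant enzymes 0 passed (1 over the list alone; 0.38 likewise; 0.17 without control C, 0.27 without rotenone A), and of 16 cytosolic heat shock proteins 0 passed (3 lower over the list alone; 0.19 likewise; 0.14 without rotenone A, 0.11 under quantile normalization). DNAJB1 stood at 10.50 ± 0.16 (SD) in rotenone and 10.44 ± 0.075 in control samples. Complex I subunits had a median of 0.056 and complexes II to V of -0.027 at 2 weeks, and neither list was shifted (adjusted p = 0.074 and 0.55). Under quantile normalization, complex I subunits and complexes II to V subunits were both shifted upward at 2 weeks (adjusted p = 6.1e-05 and 0.0010), and lists matched on expression had lower medians (-0.060 and -0.11). NDUFB8 rose by 0.39. The pro-apoptotic BCL2 family gene PMAIP1 rose by 0.72. The count of genes was 32 without rotenone 2 weeks A, 34 without rotenone C, 74 without control A, 80 without control B and 112 without control C.

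**Figure D1:**
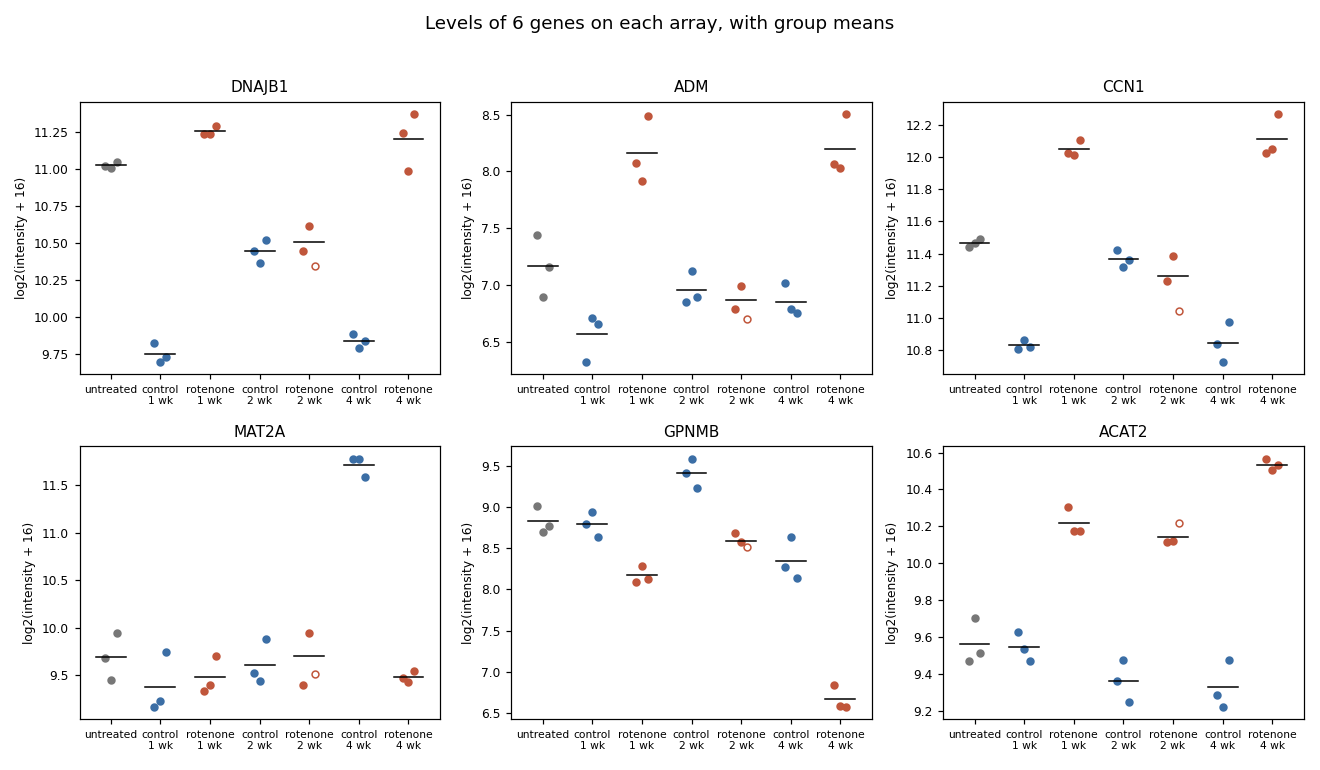
Levels of DNAJB1, ADM, CCN1, MAT2A, GPNMB and ACAT2 as log2(intensity + 16) on each of the 21 arrays, with groups along the x axis; filled points are arrays, the open point is the second labelled extract of rotenone 2 weeks A, and lines are group means. MAT2A lay between 11.581 and 11.775 in the control samples at 4 weeks, and at or below 9.9416 in the other groups, while ACAT2 was higher under rotenone at all 3 times.

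Between rotenone and control samples at 4 weeks 1570 of 14157 genes differed, 793 higher and 777 lower under rotenone, and 3346 had an unadjusted p under 0.05. The controls of that week also differed from control 1 week samples in 1964 genes. How many of the 1570 genes reflect a change in the controls was not counted. MAT2A, which makes S-adenosylmethionine, was 4.69-fold lower than in the controls of that week (log2 change -2.23 ± 0.15 SE, n = 3 against 3, adjusted p = 7.5e-10). ACAT2, a cytosolic acetyl-CoA acetyltransferase of sterol synthesis, rose 2.31-fold (1.21 ± 0.088, adjusted p = 2.8e-09), NDUFB8, a complex I subunit, rose 2.08-fold (1.06 ± 0.084, adjusted p = 9.5e-09), and DNAJB1 rose 2.57-fold (1.36 ± 0.086, adjusted p = 3.3e-10). Against untreated samples, DNAJB1 in rotenone 4 weeks samples did not pass (0.17, adjusted p = 0.20). Of the 1570 genes, 1465 had rotenone samples all on 1 side of the controls, as did 23.7% of all tested genes against 10% by chance. Median centring moved the share of higher genes from 50.5% to 64.1%.

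The low MAT2A level at 4 weeks was set by the controls: it was 11.71 ± 0.11 (SD) in control 4 weeks, 9.38 ± 0.32 in control 1 week and 9.48 ± 0.061 in rotenone 4 weeks samples. Another MAT2A probe set fell by 1.98. The other large rises were TMIGD2 (1.67), the guanylate-binding protein gene GBP1 (1.67), LINC02091 (1.53), SPTB (1.35), ADM (1.34), the glutaredoxin gene GLRX (1.33), LINC00943 (1.31), CCN1 (1.27), KCNS2 (1.25), the adenosine receptor gene ADORA2B (1.23) and the LIM domain gene FHL2 (1.23). The other large falls were GPNMB (-1.69), GARIN4 (-1.68), ANKRD53 (-1.65), OGDH (-1.55), PCDHB4 (-1.55), RERG (-1.48), ASB13 (-1.47), EMILIN3 (-1.40), CYP4F22 (-1.40), CASKIN2 (-1.36) and NPY6R (-1.35). A dimmer probe set of GPNMB changed the opposite way, by 0.90 (adjusted p = 4.9e-04 over the probe sets), so the fall holds only for the brighter probe set. With each replicate left out in turn, 7 of the 12 rises and 9 of the 12 falls passed throughout.

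At 4 weeks, 12 lists were shifted, 10 upward and 2 downward, and 3 held with an estimated correlation. Of 24 ER chaperones and unfolded protein response genes 14 fell and 0 rose (18 lower adjusted over the list alone), including HYOU1 (-1.16), SDF2L1 (-0.90), calreticulin (CALR, -0.69) and the main ER HSP70 gene HSPA5 (-0.68). The list median was -0.33 (adjusted p = 0.0010 with an estimated correlation). Of 18 cholesterol synthesis genes 9 rose and 0 fell (9 adjusted over the list alone), including DHCR7 (0.92), INSIG1 (0.65) and SC5D (0.63), with a median of 0.41 (adjusted p = 7.8e-04 with an estimated correlation). SC5D reversed to -0.11 when its probe sets were averaged. Of 27 proteasome subunits 15 rose and 0 fell (17 adjusted over the list alone), with PSMB3 at 0.64, PSMB2 at 0.48, PSMD2 at 0.46 and PSMB4 at 0.42 (list adjusted p = 0.049 with an estimated correlation).

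The lists of respiratory chain genes were also shifted upward at 4 weeks at the preset correlation only. Of 33 complex I subunits 19 rose and 0 fell (25 adjusted over the list alone), with NDUFA7 at 0.79, NDUFA1 at 0.77 and NDUFA6 at 0.67 beside NDUFB8, and a median of 0.36 (adjusted p = 0.077 with an estimated correlation). Of 35 subunits of complexes II to V 13 rose (22 adjusted over the list alone), including COX6B1 (0.53), COX7B (0.49), UQCRQ (0.46) and COX5A (0.43), with a median of 0.27 (adjusted p = 0.17 with an estimated correlation). Lists matched on expression had medians of 0.10 and 0.12. Rotenone 4 weeks B, the array with the 3' to 5' difference of 0.68 for ACTB, had the highest mean of the complex I list (11.09) and of the proteasome list (11.32). Without it, the medians were 0.30 for complex I, 0.20 for complexes II to V and 0.24 for the proteasome, and 1148 genes changed.

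The cell cycle list had 14 of 41 members higher and 2 lower at 4 weeks (15 and 4 adjusted over the list alone), with E2F1 at 1.16, TYMS at 0.83, RRM1 at 0.78 and RRM2 at 0.75. Its call was lost with an estimated correlation (adjusted p = 0.097) and under quantile normalization (0.086), where the median turned from 0.088 to -0.013. Of 30 tubulins and microtubule proteins 6 rose and 1 fell (6 and 1 adjusted over the list alone): TUBA1A rose by 1.12, TUBB2B by 0.94 and KIF5B by 0.60, and KIF5A fell by 0.96. That call was lost with an estimated correlation (adjusted p = 0.20), under quantile normalization (0.093) and without control 4 weeks C (0.13). Of 16 cytosolic heat shock proteins 4 rose and 1 fell (7 and 1 over the list alone), with HSPB1 at 0.75, CHORDC1 at 0.35 and HSF1, the main heat shock transcription factor, at -0.41 (list adjusted p = 0.077 with an estimated correlation). Against control 1 week samples, the heat shock list in rotenone 4 weeks samples had a median of -0.015, and in control 4 weeks samples of -0.15.

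ATF4 and amino acid stress targets moved both ways at 4 weeks, with 5 of 33 higher and 9 lower (5 and 10 adjusted over the list alone). DDIT3 (CHOP) fell by 0.72, WARS1 by 0.67, the amino acid transporter gene SLC7A5 by 0.67 and STC2 by 0.59. These falls are relative to controls in which the list had risen. Against control 1 week samples, 25 of 33 targets were higher and 0 lower in control 4 weeks samples (median 0.56). In rotenone 4 weeks samples, 15 were higher and 1 lower (median 0.33). The list's downward call was lost with an estimated correlation (adjusted p = 0.27) and without control 4 weeks B (0.15), rotenone B (0.10) or rotenone C (0.091). Of 29 other antioxidant enzymes 6 rose and 1 fell (8 and 3 over the list alone), with GSTP1 at 0.62, PRDX6 at 0.50 and SOD1 at 0.46 (adjusted p = 0.32 with an estimated correlation). Immediate early genes had 5 of 26 higher (6 higher and 1 lower over the list alone), with JUN at 0.86, KLF10 at 0.62 and ATF3 at 0.55; that call was lost with an estimated correlation (adjusted p = 0.12) and without rotenone C (0.078). Fatty acid oxidation and tricarboxylic acid cycle genes had 6 of 32 higher and 1 lower, also over the list alone, with HADH at 0.64 and PDHA1 at 0.45 against OGDH (adjusted p = 0.24 with an estimated correlation; 0.052 without rotenone A; 0.085 under quantile normalization). Against lists matched on expression, the 4-week medians of the cell cycle (percentile 68.4), immediate early genes (94.4), other antioxidant enzymes (89.9) and fatty acid oxidation with the tricarboxylic acid cycle (87.3) did not stand out.

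Members of lists that were not shifted at 4 weeks also changed. Of 24 NRF2 targets 4 rose, such as TXN (0.62), PRDX1 (0.46) and TKT (0.43), and 1 fell (UGDH, -0.62). Of 38 autophagy and lysosome genes 2 rose, with ATG3 at 0.51, and 3 fell (TPP1 -0.68, GRN -0.64, CTSA -0.54). Of 21 Parkinson disease genes 1 rose (PARK7, 0.25) and 3 fell, such as SMPD1 (-0.84) and SCARB2 (-0.78), and of 17 catecholamine neuron genes 1 rose (PTS, 0.49) and 1 fell (ALDH1A1, -1.08). Of 24 BCL2 family and caspase genes 3 rose, with BID at 0.42, and 2 fell (CASP8 -0.66, FADD -0.47). Of 32 extracellular matrix genes 1 rose (FN1, 0.44) and 3 fell (TIMP3 -0.89, COL4A1 -0.62, LOX -0.49).

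**Figure D2:**
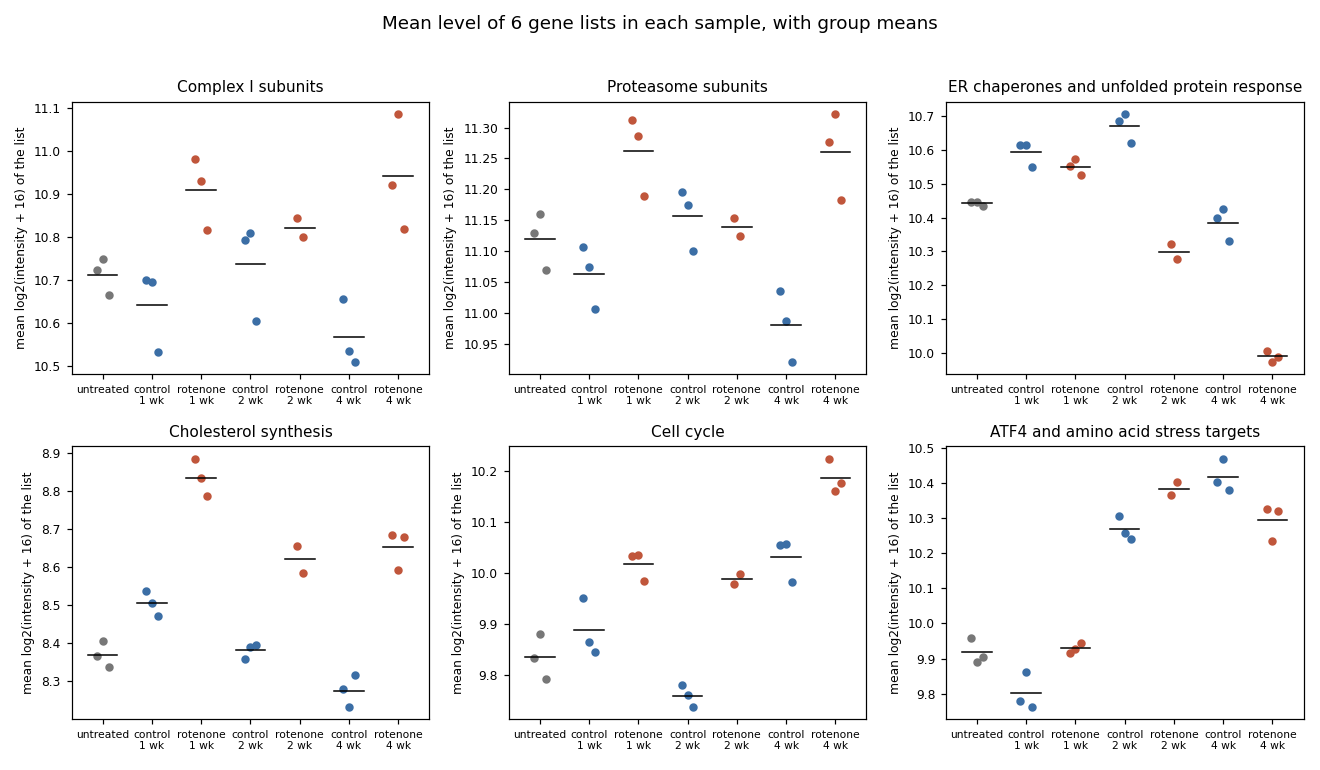
Mean log2(intensity + 16) of the members of 6 gene lists in each of the 20 samples, with groups along the x axis; points are samples and lines are group means. ER chaperones were lowest in rotenone 4 weeks samples, and the ATF4 list stood higher in control 4 weeks than in control 1 week samples (median change 0.56).

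Averaged over the 3 weeks, 1155 genes differed between rotenone and control samples, 655 up and 500 down, and 3050 genes had an unadjusted p under 0.05. ARHGDIB rose 2.05-fold (1.04 ± 0.077 SE, adjusted p = 3.6e-09), DNAJB1 by 0.98 ± 0.051, ACAT2 by 0.89 ± 0.053 and GBP1 by 0.87, while GPNMB fell by 1.04, the lysosomal protease gene CTSF by 1.07 and HELZ2 by 1.02. The dimmer GPNMB probe set changed the opposite way over the weeks too (0.35, adjusted p = 0.024 over the probe sets). The other large rises were LOC101927604 (0.99), RBM14 (0.87), C21orf58 (0.86), SCAMP1-AS1 (0.84), RAD51AP1 (0.82), PLEKHN1 (0.81), ENDOG (0.79) and CXCL10 (0.76). The other large falls were NKX6-2 (-0.90), CXCL16 (-0.88), CNTFR-AS1 (-0.85), SIRPD (-0.79), EMILIN3 (-0.78), FAM210B (-0.75), NBAS (-0.72), HYKK (-0.71) and P4HA2 (-0.71). The count fell to 693 without rotenone 2 weeks A and to 714 without rotenone 2 weeks C, and median centring moved the share of higher genes from 56.7% to 74.8%.

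Over the weeks, 12 lists were shifted upward and 1 downward, and 4 held with an estimated correlation. ER chaperones had 14 of 24 lower (17 adjusted over the list alone; median -0.26; adjusted p = 2.0e-04 with an estimated correlation), including HYOU1 (-0.68) and ERN1 (-0.45), the sensor kinase of the unfolded protein response. Cholesterol synthesis had 9 of 18 higher (13 over the list alone; median 0.29; adjusted p = 1.2e-04 with an estimated correlation), including FDPS (0.67) and DHCR7 (0.62). The cell cycle list had 17 of 41 higher (27 over the list alone; median 0.15; adjusted p = 0.0027 with an estimated correlation), and mesenchymal markers 8 of 18 (9 over the list alone; median 0.17; adjusted p = 0.0051 with an estimated correlation), with SNAI2 at 0.71 and LUM at 0.37. The mesenchymal list was not shifted at 4 weeks, where its median was -0.045 (adjusted p = 0.67). By then both arms stood above control 1 week samples. Its median against them was 0.34 in rotenone 4 weeks samples (8 of 18 higher, 0 lower). In control 4 weeks samples it was 0.33 (7 higher, 1 lower). Complex I had 19 of 33 higher (24 over the list alone; median 0.25; adjusted p = 0.053 with an estimated correlation), complexes II to V 10 of 35 (19 over the list alone; median 0.13; 0.18 likewise) and the proteasome 10 of 27 (17 over the list alone; median 0.14; 0.053 likewise). The other upward lists were glycolysis (median 0.073, adjusted p = 0.27 with an estimated correlation), other antioxidant enzymes (0.12; 0.077 likewise), heat shock proteins (0.053; 0.12 likewise), tubulins (0.060; 0.081 likewise), immediate early genes (0.018; 0.11 likewise) and fatty acid oxidation with the tricarboxylic acid cycle (0.086; 0.10 likewise). Of these, glycolysis (percentile 95.7), heat shock proteins (83.0), tubulins (96.6) and immediate early genes (84) lay within the middle 95% of lists matched on expression.

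The exact permutation of each list's mean per sample within weeks gave 13 lists with an adjusted p under 0.05, of which 12 were among the 13 shifted lists. Heat shock proteins were lost in this test (adjusted p = 0.065), and BCL2 family and caspase genes passed, upward by 0.066 (adjusted p = 0.0060). For cholesterol synthesis and the cell cycle the exact permutation test gave p = 2.5e-04 before adjustment, the smallest possible (adjusted p = 0.0040), for ER chaperones 7.5e-04 (adjusted p = 0.0060) and for complex I 0.00125 (adjusted p = 0.0080).

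Other cell type markers and several other lists were not shifted by the list test at 1, 2 or 4 weeks or over the weeks. Over the weeks, medians were 0.20 for 9 astrocyte markers (adjusted p = 0.51), -0.18 for 8 oligodendrocyte markers (0.34), -0.12 for 6 microglia and macrophage markers (0.31) and -0.072 for 7 endothelial markers (0.93). They were 0.022 for catecholamine neuron genes (0.78), -0.018 for Parkinson disease genes (0.97), 0.0068 for neuronal and synaptic genes (0.59), 0.0052 for mitochondrial biogenesis (0.57), -0.048 for hypoxia targets (0.78), 0.027 for p53 targets (0.73), 0.044 for BCL2 family and caspase genes (0.065), -0.0054 for autophagy and lysosome genes (0.96), -0.028 for interferon response genes (0.93), 0.13 for inflammatory and NF-kB targets (0.15) and -0.072 for metallothioneins (0.73). Against lists matched on expression, the medians of astrocyte markers (percentile 99.7) and inflammatory and NF-kB targets (99.95) were high. Random lists do not carry the correlation between members of a list, so these percentiles can overstate a shift. In the exact permutation of list means over the weeks, neither list passed (adjusted p = 0.40 and 0.38). Some medians were low without a call in that comparison: ribosomal proteins over the weeks (percentile 0.59), extracellular matrix at 4 weeks (0.61) and NRF2 targets at 2 weeks (1.55).

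Among genes called in separate weeks, which share no samples, more had the same direction than independent lists would share. The calls are still not independent, because every week uses the same estimate of each gene's spread from 1 fit. A gene of low spread can therefore pass in several weeks, so the numbers for independent lists are only a reference. Over all genes the changes correlated weakly (r = 0.21 for 1 and 4 weeks, 0.054 for 1 and 2 weeks, 0.040 for 2 and 4 weeks). Genes are not independent replicates. Between 1 and 4 weeks 74 higher genes were common, where independent lists would share 7.67, and 22 lower genes, where they would share 2.96. Between 1 and 2 weeks 17 higher and 3 lower genes were common (1.12 and 0.20 for independent lists), and between 2 and 4 weeks 27 higher and 18 lower (6.50 and 2.91). Opposite directions were found in 4 of 100 genes called at both 1 and 4 weeks, and in 19 of 64 called at both 2 and 4 weeks. For 1 and 2 weeks it was 1 of 21. These counts were not set against independent lists. The 13 genes called in all 3 weeks were ACAT2, ALDH7A1, ARHGDIB, ATF3, EIF2B3, FDPS, GRP, RNASEH2C, TNFAIP6 and TYMS, which were higher each time, ZNF703 and (by its brighter probe set only) GPNMB, which were lower each time, and OSER1, which rose at 1 and 4 weeks and fell by 0.38 at 2 weeks.

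The rotenone effect itself differed between weeks for 655 genes (4 against 2 weeks), 110 genes (4 against 1 week) and 24 genes (2 against 1 week). The rises of DNAJB1, CCN1 and ADM at 1 week were absent at 2 weeks. Differences between those effects were -1.44 ± 0.13, -1.32 ± 0.12 and -1.68 ± 0.27 (SE), with adjusted p = 6.9e-07, 6.9e-07 and 0.0051. Both arms contributed. From 1 to 2 weeks, control means went from 9.75 to 10.44 (DNAJB1), 10.83 to 11.37 (CCN1) and 6.57 to 6.96 (ADM). Rotenone means went from 11.25 to 10.50, 12.05 to 11.26 and 8.16 to 6.87, in the same order. E2F1 rose more at 4 weeks than at 1 week, by 1.16 ± 0.25 (adjusted p = 0.021).

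Control samples also changed with time, in 462 genes from 1 to 2 weeks and in 1096 from 2 to 4 weeks. The 4-week controls also serve in the rotenone comparison of that week, so the counts that use them are not independent. Between control 4 weeks and control 1 week 1964 genes changed, more than between rotenone and control samples in any week. Of these, 1098 were up and 866 down, and 3650 genes had an unadjusted p under 0.05. MAT2A rose 5.03-fold (2.33 ± 0.15 SE, n = 3 against 3, adjusted p = 2.9e-10), the splicing regulator gene ESRP1 rose 3.68-fold (1.88 ± 0.093, adjusted p = 1.2e-12), and TMEM129 (2.51), LINC00968 (2.11) and FGF12 (1.88) rose. NOMO3 (-1.74), PEX11G (-1.55), POLM (-1.45), HMCN2 (-1.44) and GRIN1 (-1.35) fell; of these falls, NOMO3 passed with each replicate left out in turn.

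In the controls over time, 4 lists moved up and 6 down, and 5 held with an estimated correlation. ATF4 and amino acid stress targets had 25 of 33 higher and 0 lower (25 adjusted over the list alone; median 0.56; adjusted p = 0.0011 with an estimated correlation). Mesenchymal markers had 7 of 18 higher and 1 lower (11 and 1 over the list alone; median 0.33; 0.019 likewise), and extracellular matrix genes 9 of 32 higher (9 higher and 1 lower over the list alone; median 0.13; 0.048 likewise). ER chaperones had 10 of 24 lower (11 over the list alone; median -0.20; 0.035 likewise), and cholesterol synthesis 6 of 18 lower (9 over the list alone; median -0.24; 0.031 likewise). The cell cycle list moved up with 15 higher and 8 lower (adjusted p = 0.35 with an estimated correlation). Complexes II to V (median -0.12; 0.82 likewise), heat shock proteins (-0.15; 0.37 likewise), autophagy and lysosome (-0.16; 0.45 likewise) and ribosomal proteins (-0.12; 0.82 likewise) moved down.

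Between control 1 week and untreated samples 35 genes changed, 16 up and 19 down, and 1383 had an unadjusted p under 0.05. HSPA6 was 3.24-fold lower in the controls (-1.69 ± 0.18 SE, n = 3 against 3, adjusted p = 1.2e-05) and DNAJB1 2.42-fold lower (-1.27 ± 0.086, adjusted p = 1.9e-09), and PTX3 (-0.89), KLHDC7B (-0.72) and RASSF1 (-0.70) were lower. The mitotic kinase gene MASTL (0.81), APELA (0.80), C4orf46 (0.76), lamin B1 (LMNB1, 0.67) and the kinesin gene KIF14 (0.64) were higher. Cytosolic heat shock proteins had 1 of 16 lower (6 lower and 1 higher adjusted over the list alone; median -0.14; adjusted p = 0.035 with an estimated correlation). ER chaperones moved up, with 0 of 24 passing (8 over the list alone; median 0.17; 0.019 likewise), as did cholesterol synthesis, with 1 of 18 higher (1 over the list alone; median 0.12; 0.047 likewise). Complex I (median -0.076), ATF4 targets (-0.097), the proteasome (-0.059), tubulins (-0.091) and immediate early genes (-0.14) moved down at the preset correlation, with adjusted p = 0.82, 0.098, 0.76, 0.36 and 0.25 with an estimated correlation. The count was 16 without untreated A and 16 without control 1 week A; the share of higher genes was 45.7%, and 27.8% under median centring and 59.3% under quantile normalization.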

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

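Of the tests on the 3 patterns weighed here, those on the share kept without the sample of low RNA quality, on shared handling and on other splits of the samples were fixed before their results were seen, and the others were chosen afterwards. The results listed are those in which the rotenone effect differed between weeks by a test of the difference itself. Higher and lower effects are compared there with their sign. A higher effect can therefore be a weaker fall, and a lower effect a stronger fall.

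The rotenone effect differed between 4 and 1 weeks for 110 genes (signed effect higher at 4 weeks in 41, lower in 69). The signed effect was higher for SLN (1.97), LOC100505715 (1.87), EPN1 (1.59), MASTL (1.33) and E2F1 (1.16). It was lower for MAT2A (-2.33), LINC02551 (-1.81), CYP4F22 (-1.58), ESRP1 (-1.25) and SELENON (-1.24). The MAT2A effect, for example, went from 0.097 at 1 week to -2.23 at 4 weeks. MASTL, MAT2A and ESRP1 passed with each replicate left out. Of 200 splits of the week 1 and week 4 samples 100 were drawn, and 9 of them, the real one included, gave at least 110 genes, up to 853. The other 8 each kept or exchanged all labels of a whole week and so carry the effect of rotenone itself, and these splits do not test chance here. The median of complex I was higher by 0.11, while hypoxia targets (-0.11), ATF4 targets (-0.19), ER chaperones (-0.28), extracellular matrix (-0.22) and mesenchymal markers (-0.36) were lower. With an estimated correlation, the last 4 of these calls held (adjusted p = 0.030, 0.0060, 0.019 and 0.024), and those of complex I (0.82) and hypoxia targets (0.15) were lost. The count was 56 without rotenone 1 week B, 68 without control 1 week A and 68 without control 1 week C. It was 64 without control 4 weeks B and 183 without control 4 weeks C. Median centring moved the share of higher signed effects from 37.3% to 19.7%.

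Between 2 and 1 weeks the effect differed for 24 genes. The signed effect was higher at 2 weeks for KLF15 (1.29), LINC00968 (1.19), CSTF3 (1.09), BHLHE22 (0.99) and HOOK1 (0.92). It was lower for ADM (-1.68), DNAJB1 (-1.44), HSPA6 (-1.38), CCN1 (-1.32) and ACTG2 (-0.76). DNAJB1 and CCN1 passed with each replicate left out. List medians were lower for complex I (-0.21), complexes II to V (-0.24), glycolysis (-0.13), NRF2 targets (-0.29), ER chaperones (-0.32), proteasome (-0.21), heat shock proteins (-0.41), tubulins (-0.18), autophagy and lysosome (-0.093), ribosomal proteins (-0.32) and fatty acid oxidation with the tricarboxylic acid cycle (-0.12). With an estimated correlation, the calls of ER chaperones (adjusted p = 0.0031) and heat shock proteins (0.016) held. The others were lost, in the order above without these, at adjusted p = 0.46, 0.41, 0.49, 0.054, 0.16, 0.21, 0.49, 0.32 and 0.41 with an estimated correlation, and the glycolysis median turned to 0.0073 under quantile normalization. Leaving out 1 sample gave from 3 genes (rotenone 2 weeks C) and 6 (rotenone 2 weeks A), through 7 (control 2 weeks A), 11 (rotenone 1 week B), 12 (control 1 week B), 12 (control 2 weeks B), 13 (control 1 week C) and 15 (rotenone 1 week A), to 28. The share of higher signed effects was 41.7%, against 9.09% under median centring and 64% under quantile normalization. Median centring moved the median of all genes from 0.046 to -0.10.

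Between 4 and 2 weeks the effect differed for 655 genes. The signed effect was higher at 4 weeks for AQP1 (1.94), ADM (1.43), CCN1 (1.37), FHL2 (1.36) and ACTG2 (1.35). It was lower for ANKRD53 (-2.59), TMEM129 (-2.33), MAT2A (-2.31), PCDHB4 (-1.77) and SLC13A3 (-1.57). ADM, CCN1, FHL2, ACTG2 and MAT2A passed with each replicate left out. List medians were higher for complex I (0.32), complexes II to V (0.28), NRF2 targets (0.17), proteasome (0.28), heat shock proteins (0.41), immediate early genes (0.050) and ribosomal proteins (0.28), and lower for ATF4 targets (-0.25) and extracellular matrix (-0.23). With an estimated correlation, the call of heat shock proteins held (adjusted p = 0.037), and those of complex I (0.35), complexes II to V (0.38), NRF2 targets (0.33), proteasome (0.11), immediate early genes (0.36), ribosomal proteins (0.45), ATF4 targets (0.15) and extracellular matrix (0.054) were lost. The count was lowest without rotenone 2 weeks C or A, each of which leaves a lone rotenone sample at 2 weeks. It was 361 without control 2 weeks B and 389 without control 2 weeks A. Median centring moved the share of higher signed effects from 55.6% to 76.4%.

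Subunits of the respiratory chain and the proteasome were higher at 1 and 4 weeks of an inhibitor of complex I, but with an estimated correlation the calls were lost for complex I (adjusted p = 0.077 in both weeks), complexes II to V (0.18 and 0.17) and the proteasome at 1 week (0.053). A trend with brightness is argued against, since their medians lay at or above percentile 99.5 of lists matched on expression; complex I and complexes II to V stood about as high at 2 weeks (99.9 and 99.5), so brightness stays open for their differences between weeks. Rotenone 4 weeks B, with its high 3' to 5' difference for ACTB, is argued against as the only cause of the 4-week rise, because rotenone A and C lay above all controls of that week by at least 0.10 in the mean of each list (SD 0.068), and for complex I over the weeks so are members that move together by chance (exact permutation p = 0.00125). How much that sample adds to the 4-week rise stays open: without it, the lowest of the 3 list medians kept a share of 0.754 of its value (SD of such shares 0.14). A response to rotenone may account for these rises as a hypothesis, and handling that differed between the arms was not tested.

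MAT2A set the 4-week controls apart from all other samples, and ATF4 targets were higher in them than in control 1 week samples. The ATF4 rise over control 1 week was not particular to them. At 2 weeks 17 of 33 targets were already higher in control samples (median 0.37) and 20 in rotenone samples (median 0.50), with 0 lower in either. For MAT2A a single deviating array is argued against, because the lowest 4-week control lay 1.64 (log2) above the highest of all other samples (SD of the 4-week controls 0.11), and so is a fault of 1 probe set, because another one rose by 2.26 (adjusted p = 9.0e-09). Amino acid shortage in the 4-week controls alone could raise ATF4 targets, but the lowest rotenone 4 weeks sample lay 0.37 above the highest control 1 week sample in the mean of that list (SD 0.053), so most of the rise was shared by both arms. What raised MAT2A in the controls and not under rotenone stays open. If the samples were cultures, which the labels do not say, this includes culture density and time since feeding, for which the labels give nothing.

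DNAJB1, HSPA6, CCN1 and ADM were higher in rotenone than in control samples at 1 and 4 weeks, and all but ADM were also higher in untreated than in control 1 week samples. Rotenone alone is argued against for DNAJB1, since control 1 week and untreated samples, neither exposed, differed by -1.27 (adjusted p = 1.9e-09). ADM differed by -0.60 (adjusted p = 0.19). Against untreated samples, rotenone samples were still higher in CCN1 at 1 and 4 weeks (0.58 and 0.65, adjusted p = 2.2e-04 and 5.4e-06). The same held for ADM (0.99 and 1.03, adjusted p = 0.0036 and 3.2e-04). A rotenone effect thus stays open for CCN1 and ADM. HSPA6 was not higher than in untreated samples at either time (-0.50 and -0.18, adjusted p = 0.18 and 0.59). DNAJB1 did not pass against them (0.23 and 0.17, adjusted p = 0.19 and 0.20). A state of handling or harvest shared by untreated and rotenone samples may raise such stress genes. Of 32 other genes that differed between control 1 week and untreated samples, 43.8% had the opposite sign in rotenone against control at 4 weeks (exact binomial 95% interval 26.4% to 62.3%, highest other split 62.5%). This share met the limit fixed beforehand against such a state, and the interval lay below the share the state was to give. But the interval reaches past the limit against it and treats genes as independent. The value argues only weakly against a state shared by these other genes, and leaves DNAJB1, HSPA6, CCN1 and ADM open.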

How the results depend on the processing

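Leaving out a week, the exact permutation of list means and the matched random lists were chosen after the results were seen; the other alternatives were planned. Of 452 pairs of a named gene and a comparison, with control 2 weeks against the other control weeks left out, 367 passed, and 130 of these passed under every alternative and with every replicate left out, 216 lost the threshold under at least 1 alternative and 167 when a replicate was left out. Causes were not tested unless stated. The large falls at 1 week were all of dim genes.

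With an estimated correlation between genes, shifted lists numbered 5 at 1 week, 4 at 2 weeks, 3 at 4 weeks and 4 over the weeks; this alternative lost 34 of the 50 list calls. Of the same 50 calls, 11 were lost against random lists matched on expression and 6 under quantile normalization, and pseudocounts and filters lost at most 1 each. The exact permutation of list means, made over the weeks only, lost 1 of 13. Counts of changed genes that moved by over 1.5 times were as follows, at 1, 2 and 4 weeks where given. The mean of all probe sets of a gene gave 99, 102 and 920 genes, 57 (4 against 1 week), 9 (2 against 1), 262 (4 against 2) and 23 (control 1 week against untreated). Without the intensity trend there were 38 at 1 week and 65 at 2 weeks, and 44, 9, 251 and 10 for the same last 4 comparisons. Array weights gave 315 at 1 week, 672 at 2 weeks, 183 (2 against 1), 1172 (4 against 2) and 72 (untreated). Median centring gave 58 at 2 weeks, 61 (4 against 1), 11 (2 against 1), 343 (4 against 2) and 18 (untreated), and quantile normalization 178 (4 against 1) and 59 (untreated). The filter at the 60th percentile gave 53 (untreated), with fewer genes tested. With only the 2 groups compared in the fit there were 290 at 2 weeks and 510 at 4 weeks, with fewer samples for the spread. Pooling untreated and control 1 week gave 346 at 1 week. The second labelled extract kept as a separate sample gave 378 at 2 weeks and 65 (2 against 1). Over the weeks, 696 genes changed without week 1 and 354 without week 4. Pseudocounts, no filter and leaving the second extract out moved no count by over 1.5 times.

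With the replicate letter as a block, 363 genes changed at 1 week, 215 in 4 against 1 week, 71 in 2 against 1 week and 85 between control 1 week and untreated, and no other count moved by over 1.5 times. The letters are not known to pair samples: over 14 pairs, deviations of same-lettered samples correlated at -0.049 to 0.066, 0 pairs were over 0.1, and 8 correlated best with their own letter.

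With each replicate left out in turn, counts ranged from 27 to 251 at 1 week, 32 to 112 at 2 weeks and 1148 to 1472 at 4 weeks, where they stayed within 1.5 times. They ranged from 693 to 1220 over the weeks, 56 to 183 (4 against 1 week), 3 to 28 (2 against 1), 174 to 643 (4 against 2), 1449 to 1709 (control 4 weeks against 1 week) and 16 to 35 (control 1 week against untreated). A lone sample left in a group is assumed to vary like the others. Shifted lists ranged from 15 to 16, 6 to 10 and 11 to 13 at the 3 times.

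Directions turned when all probe sets of a gene were averaged: at 1 week ATP5PD (-0.085), ATF3 (-0.079), DNAJC3 (0.026) and CFLAR (-0.050), at 2 weeks SLC30A1 (-0.040), at 4 weeks SC5D (-0.11) and HRK (-0.072), and over the weeks ATP5PD (-0.030), PFKP (-0.097), GSTM3 (-0.055), CFLAR (-0.011) and RPS14 (0.018). RPS14 also turned without week 2 (0.011). Of the reversed pairs 8 had passed and 4 had not: DNAJC3 and CFLAR at 1 week, SLC30A1 at 2 weeks and RPS14 over the weeks.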

Other observations

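The tests of the time course were chosen after the results were seen, while the counts over other splits of the samples were planned.

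Set against control 1 week samples, rotenone 4 weeks samples had 18 of 24 ER chaperones and unfolded protein response genes lower (median -0.52), and control 4 weeks samples had 10 lower (median -0.20), and against untreated samples the control 4 weeks median was -0.057, with 5 lower and 1 higher, so the fall in the controls depends on the baseline. For cholesterol synthesis the arms parted: against control 1 week, 6 of 18 genes were lower in the controls at 4 weeks (median -0.24) and 3 were higher under rotenone (median 0.093). Against untreated samples the cholesterol median of control 4 weeks samples was -0.049. NDUFB8 also parted, at -0.59 in controls and 0.47 in rotenone samples at 4 weeks (adjusted p = 2.9e-05 and 4.4e-04). Complex I subunits had a median of -0.056 in controls, with 4 of 33 lower and 1 higher, and of 0.30 in rotenone samples, with 16 higher. For the cell cycle list the median was 0.12 in controls and 0.31 in rotenone samples, with 15 of 41 members higher and 8 lower in controls, and 19 higher and 1 lower in rotenone samples. Cytosolic heat shock proteins in rotenone 4 weeks samples had a median of -0.015 against control 1 week (2 of 16 higher, 1 lower) and of -0.14 against untreated samples (0 higher, 5 lower), while control 4 weeks samples had a median of -0.40 against untreated (0 higher, 9 lower).

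A hypothesis was that rotenone samples run ahead of the controls along the controls' own time course. Of the 1964 genes that changed between control 4 weeks and control 1 week, 1609 had the same sign in rotenone against control at 2 weeks (81.9%; the other 9 splits of those samples gave from 20.9% to 64.3%), and of the 121 that passed in both, 119 had the same sign. These comparisons share no samples. The share the hypothesis needs was seen at 2 weeks, but with 10 splits, the lowest nearly as far on the opposite side, chance is not excluded. At 4 weeks the opposite was seen: of the 462 genes that changed between control 2 weeks and control 1 week, 36.1% had the same sign in rotenone against control (26 of the 129 that passed in both), but other labellings of those samples gave shares from 31.8% to 68.2%, so this value decides nothing. A difference in the state of the 2-week controls, whose cell cycle mean was the lowest of all groups in the plot of list means, may also give the 2-week value and was not tested.

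Other splits of the same samples were counted for the comparisons below, with the real labels as 1 of the splits. For the mean over the weeks, 100 splits were drawn from 4000, and only the real labels gave as many as 1155 genes (highest other 239). Chance assignment of these samples is argued against, but not excluded. If the replicates are technical, differences beyond these samples are not covered. For rotenone against control there were 10 splits at 1 week (1 as large; 191 genes, highest other 0) and 10 at 4 weeks (1 as large; 1570, highest other 0). There were also 10 for control 4 weeks against control 1 week (1 as large; 1964, highest other 1) and 10 for control 1 week against untreated (1 as large; 35, highest other 1). With 10 splits, a share under 0.05 cannot be reached.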
